A study of Mus musculus with 4 samples.

How the data were processed

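RNA was measured by poly(A) sequencing in 4 mouse libraries, 2 from animals carrying the CD11c-cre transgene alone (Ctrl) and 2 from animals that also carried loxP-flanked Il33 alleles on both chromosomes (Il33flx). Cre driven from the CD11c promoter acts in dendritic cells (DCs) and some other myeloid cells. Per the labels, every animal had carried EL4-Flt3 tumour cells for 10 days, and cells of spleen and mesenteric lymph node were sorted as positive for CD45, CD11b, CD103 and MHC class II and negative for CD64. RNA was taken with a Qiagen RNeasy plus kit and libraries were made with an Illumina TruSeq mRNA kit, per the labels' protocols. The labels do not say whether the libraries of a group came from separate animals or pools, so p-values measure the spread between these libraries, which may be partly technical.

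The main values were the deposited gene counts, whole-number read counts per gene that the authors had not normalized. Per the submitters' processing notes, Trimmomatic 0.39, STAR, HTSeq and DESeq2 were used with genome build GRCm38. The versions of the last 3 tools, the annotation release, the strand setting and the read length were not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping gene on the opposite strand cannot be told apart. Among the genes with the smallest p, Gdpd3, Wdfy1, Bank1, Sult1a1, Fkbp5, Slc44a1 and Slc22a23 overlap such a gene. The count table held 46078 gene rows and 5 HTSeq summary rows. The summary rows named no gene and stayed out of library sizes and tests. Of all counted reads per library, 69.9% to 72.2% were in genes, 21.9% to 23.1% did not align uniquely, 3.22% to 4.93% overlapped no feature and 2.62% to 2.74% were ambiguous between genes. Reads of near-identical copies can therefore be lost or split, and values of such genes are uncertain.

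The authors' deposited table of their own DESeq2 comparison listed 15001 genes. Its per-library signal columns were the deposited counts divided by 1 size factor per library, which was checked against the count table. Its log2 columns were the authors' fold change of Il33flx over Ctrl and the standard error of that change, its score column was the authors' Wald statistic, and its p-value columns were the authors' unadjusted and adjusted p-values. Whether fold changes had been shrunken and which filter set the listed genes was not given in the sources used here. These values were used only where the text names the authors' deposited table.

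Gene identifiers were matched to GENCODE M21 of the same build, which named 45229 of the rows and supplied coordinates and gene classes. Libraries held 67707682 to 81217828 gene counts. A count of 3, taken as the limit that a count of 0 allows, was worth 0.0369 to 0.0443 CPM (counts scaled to a fixed total per library). Intervals and such limits cover counting error only, since reads made by PCR are not independent molecules.

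Il33flx was compared with Ctrl by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with the filterByExpr filter, TMM factors and no covariate. Of the gene rows, 14995 passed the filter. P-values were adjusted by the Benjamini-Hochberg method and genes were called below 0.05. Standard errors are the log2 fold change divided by the square root of F. Values per library are TMM-normalized CPM, given as mean ± SD of 2 libraries. With 2 libraries against 2, a gene's groups lie apart in a given direction in 16.7% of random orderings, and a permutation test of a single value could not go below a two-sided p of 0.333, so none was run. Spread between libraries corresponded to a biological coefficient of variation of 28.6%.

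Gene lists for DC subsets, the pathways named in the text and other cell types that the gate could hold were written before the data were examined, 35 in all. Lists with at least 5 tested members, 34 of them, were tested against the remaining genes with camera of limma 3.58.1, with a preset correlation between genes of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry, a rotation test of whether a list moves one way on balance, were run beside it. Within each list, p-values were also adjusted over the list alone.

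The rule for named genes was fixed at the same time. Il33 was always reported. With fewer than 10 genes called, the rule took the 8 genes with the smallest unadjusted p in each direction among named genes of at least 5 CPM in the higher group, leaving out gene models, pseudogenes and immunoglobulin or T cell receptor segments. It also took up to 4 members with the smallest p from each list, and the genes of the gate and of DC identity. Some genes that the rule took are not reported here.

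The procedure was tested on simulated counts with the means and library sizes of these libraries, the spread that edgeR estimated per gene, and 200 genes changed by known amounts. At adjusted p below 0.05 edgeR recovered 12 of 80 genes changed 2-fold, 46 of 55 changed 4-fold and 64 of 65 changed 8-fold among 14602 genes, with 11 false calls. DESeq2 1.42.0 recovered 24, 50 and 64 of them with 49 false calls among 14995 genes. False calls were thus a larger share of the DESeq2 calls than of the edgeR calls, and well above the 0.05 that the threshold sets. A call with DESeq2 alone therefore carries less weight than its adjusted p, though this rests on a single draw with the spread estimated by edgeR. With 200 genes changed, the adjusted threshold is also easier to reach, so recovery would be lower where few genes change. Wdfy1, 8.43-fold higher in Il33flx in the libraries themselves, had an adjusted p of 0.272 in edgeR. In a separate draw of the same kind, without those changes, the B cell list was raised 2-fold. Camera gave it an adjusted p of 3.99e-28 with the preset correlation and 0.22 with the estimated one. With the preset correlation it called 0 other lists. A missing call with the estimated correlation thus does not show that a list is unchanged, and fry was not tested in this way. Genes were drawn independently of each other, so neither simulation shows how the tests behave where genes vary together.

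Alternatives were DESeq2 and limma-voom in place of edgeR, robust moderation, RLE factors or library size alone in place of TMM, no filter beyond 1 count over the libraries, a filter of 1 CPM in 2 libraries, a threshold of 0.1, the replicate number as a block, and leaving out each library in turn. In the last case the lone library of a group is assumed to vary like those of the other group. No label pairs the replicate numbers, and a block on them leaves little to measure spread, so calls with it add no support. Figures were drawn with matplotlib 3.10.9.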

Results

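The study asked how transcription in CD103-positive DCs differs between mice whose CD11c-expressing cells can lose Il33 and mice that carry the Cre transgene alone. IL-33 is a cytokine of the IL-1 family that is stored in the nucleus and signals through the receptor ST2, encoded by Il1rl1. Gene counts were available for 2 Ctrl and 2 Il33flx libraries of sorted cells from spleen and mesenteric lymph node of mice bearing EL4-Flt3 cells, a derivative of the mouse T lymphoma line EL4. Library totals were 81217828 counts in Ctrl 1, 75094424 in Ctrl 2, 67707682 in Il33flx 1 and 69983532 in Il33flx 2. H2-Ab1, the MHC class II beta chain, was the most abundant gene in each library and took 3.45% to 4.04% of the counts.

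The targeted gene, Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718 on the plus strand of GRCm38), was close to the detection limit in both groups. It had 4 counts in Ctrl 1, 8 in Ctrl 2, 4 in Il33flx 1 and 0 in Il33flx 2. The ratio of Il33flx to Ctrl was 0.378, with a 95% exact counting interval of 0.089 to 1.25 and a two-sided exact binomial p of 0.13. A difference was not detectable at this depth, so the gene does not check the labels, and counts over whole genes do not show which exons remain. Il33 did not pass the filter of the main test. Without a filter, its fitted log2 fold change was -1.44 (adjusted p = 0.905, edgeR). Il1rl1 was also near the limit, at 0.501 ± 0.0816 CPM in Ctrl and 0.602 ± 0.611 CPM in Il33flx (SD, n = 2 each, adjusted p = 0.995, edgeR).

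The genes that define the sorted population were read in all libraries. Ptprc, which encodes CD45, had 563 to 1012 CPM, Itgam (CD11b) 97.8 to 128 CPM and Itgae (CD103) 56.8 to 116 CPM. Fcgr1, which encodes the excluded CD64, had 3.66 to 5.50 CPM. Genes of conventional type 1 DCs were high, with Xcr1 at 506 to 841 CPM and Clec9a at 99.8 to 120 CPM, and Sirpa, a type 2 DC gene, stood at 258 to 319 CPM. Flt3, the receptor for the DC growth factor Flt3 ligand, was at 837 ± 81.7 CPM in Ctrl and 767 ± 125 CPM in Il33flx. None of these genes was called (adjusted p = 0.995 for each, edgeR). Itgax, which encodes CD11c and whose promoter drives the Cre transgene, was lower in both Il33flx libraries, at 383 ± 34.0 CPM against 582 ± 91.6 CPM in Ctrl (log2 fold change -0.60 ± 0.19 SE, unadjusted p = 0.0182, adjusted p = 0.995, edgeR).

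The libraries did not separate by genotype first. The first principal component, 50.0% of the variance in log2 CPM, set Ctrl 1 at -70.1 against 18.8 for Ctrl 2, 26.2 for Il33flx 1 and 25.2 for Il33flx 2. Across genes, the log2 CPM of Ctrl 1 correlated with the other libraries at r = 0.969 to 0.970, whereas Ctrl 2 and the Il33flx libraries correlated with each other at 0.979 to 0.983. Genes are not independent replicates, and these correlations only describe the libraries.

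**Figure D1:**
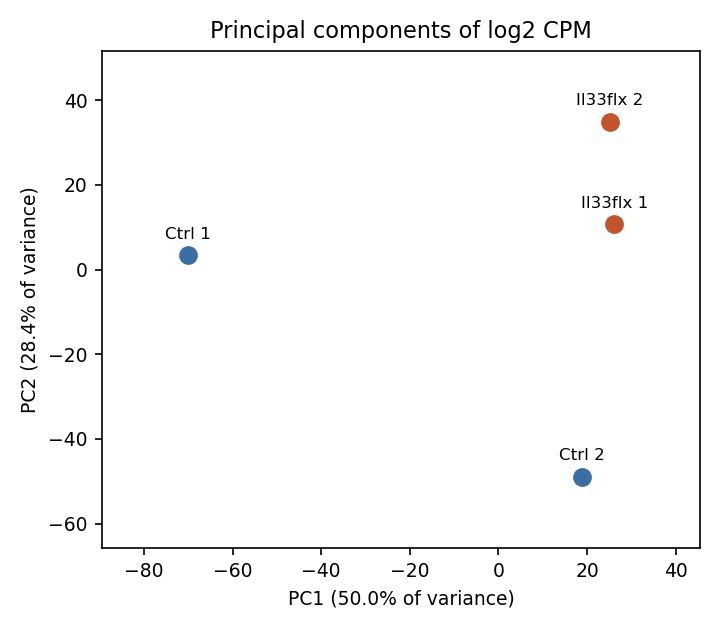
Principal components 1 and 2 of log2 CPM over the tested genes, 1 point per library (blue, Ctrl; orange, Il33flx), in arbitrary units with the percent of variance on each axis. Ctrl 1 lies at -70.1 on the first component and the other libraries between 18.8 and 26.2.

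Gdpd3, a glycerophosphodiester phosphodiesterase gene (ENSMUSG00000030703, chromosome 7, 126766334 to 126775649), was nearly absent in Ctrl and expressed in both Il33flx libraries. It had 2 and 3 counts in the Ctrl libraries and 731 and 456 in the Il33flx libraries, a ratio of 255 with a 95% exact counting interval of 109 to 787. It was the only gene called of 14995 tested (adjusted p = 0.0458, edgeR), higher in 2 of 2 Il33flx libraries, and 0 genes were called lower. At an unadjusted p under 0.05 stood 489 genes, 3.26% of those tested. DESeq2 called 31 genes higher and 22 lower, and 20 of these 53 were immunoglobulin genes. limma-voom called 0. Gdpd3 was not called without Ctrl 2, a fit that rests on Ctrl 1, the library set apart on the first principal component. Calls missing in that fit, here and below, therefore decide nothing on single genes. Without Ctrl 1 and without Il33flx 1 more genes were called than with all libraries, and most of those were immunoglobulin genes. Immunoglobulin segments varied widely between libraries of the same group.

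Beyond Gdpd3, the genes with the smallest p that were higher in both Il33flx libraries did not pass the adjusted threshold in edgeR. Wdfy1, which encodes a FYVE-domain protein of endosomes (chromosome 1, 79702262 to 79776143), had 6.33 ± 0.50 CPM in Ctrl and 53.4 ± 22.9 CPM in Il33flx (log2 fold change 3.08 ± 0.34 SE, adjusted p = 0.272, edgeR). It was called with DESeq2 (adjusted p = 2.03e-14) and by edgeR with the replicate number as a block (0.00011), without Ctrl 1 (0.00213) and without Il33flx 1 (3.5e-05), but not without Ctrl 2 (0.119) or Il33flx 2 (0.248). The long noncoding RNA Neat1, the scaffold of paraspeckles, had 44.4 ± 3.30 CPM and 82.9 ± 1.46 CPM. The B cell genes Bank1 and Cr2, the calcium channel gene Cacna1e and the extracellular matrix gene Coch had log2 fold changes of 1.06 to 1.47. The adjusted p of Neat1 and Coch was 0.873 and that of Bank1, Cr2 and Cacna1e was 0.995 in edgeR. Of these 5 genes, Coch, Cacna1e and Cr2 were called with DESeq2 (adjusted p = 0.00795 to 0.0376).

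Genes lower in both Il33flx libraries likewise did not pass the adjusted threshold in edgeR with all libraries and no block. Rnaset2b, which encodes a T2-family ribonuclease (chromosome 17, 6970634 to 7011299), had 11.2 ± 4.45 CPM in Ctrl and 0.452 ± 0.239 CPM in Il33flx (log2 fold change -4.63 ± 0.52 SE, adjusted p = 0.272, edgeR). It was called with DESeq2 (adjusted p = 6.85e-19) and by edgeR with the block (0.00014), without Ctrl 1 (0.00121) and without Il33flx 1 (0.00134), but not without Ctrl 2 (0.119) or Il33flx 2 (0.231). Rnaset2b shares sequence with the nearby Rnaset2a, so its count is uncertain. Mpeg1, which encodes the pore-forming protein perforin-2 (ENSMUSG00000046805, chromosome 19, 12460779 to 12465283), had 1146 ± 370 CPM in Ctrl and 375 ± 42.0 CPM in Il33flx. Its log2 fold change was -1.61 ± 0.26 SE with a 95% interval of -2.24 to -0.99 (unadjusted p = 0.000608, adjusted p = 0.636, edgeR). Adjusted over the list alone, Mpeg1 was 1 of 13 tested genes for pore-forming and membrane rupture proteins to pass (adjusted p = 0.0079, edgeR), while 0 of them passed over all genes tested. Mpeg1 was called with DESeq2 (adjusted p = 5.4e-05) and by edgeR with the block (-1.58, adjusted p = 0.0164). Without Ctrl 1, it was called at a log2 fold change of -1.90 (adjusted p = 0.000215, edgeR). It was not called without Ctrl 2 (-1.25, adjusted p = 0.119), without Il33flx 1 (-1.73, adjusted p = 0.182) or without Il33flx 2 (-1.48, adjusted p = 1). The sulfotransferase gene Sult1a1, the glucocorticoid receptor co-chaperone gene Fkbp5, Wdr11, the choline transporter gene Slc44a1, the proton pump gene Atp6v0c and the transporter gene Slc22a23 had log2 fold changes of -1.06 to -0.79 (adjusted p = 0.961 to 0.995, edgeR), and of these Sult1a1 was called with DESeq2 (adjusted p = 0.0292).

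**Figure D2:**
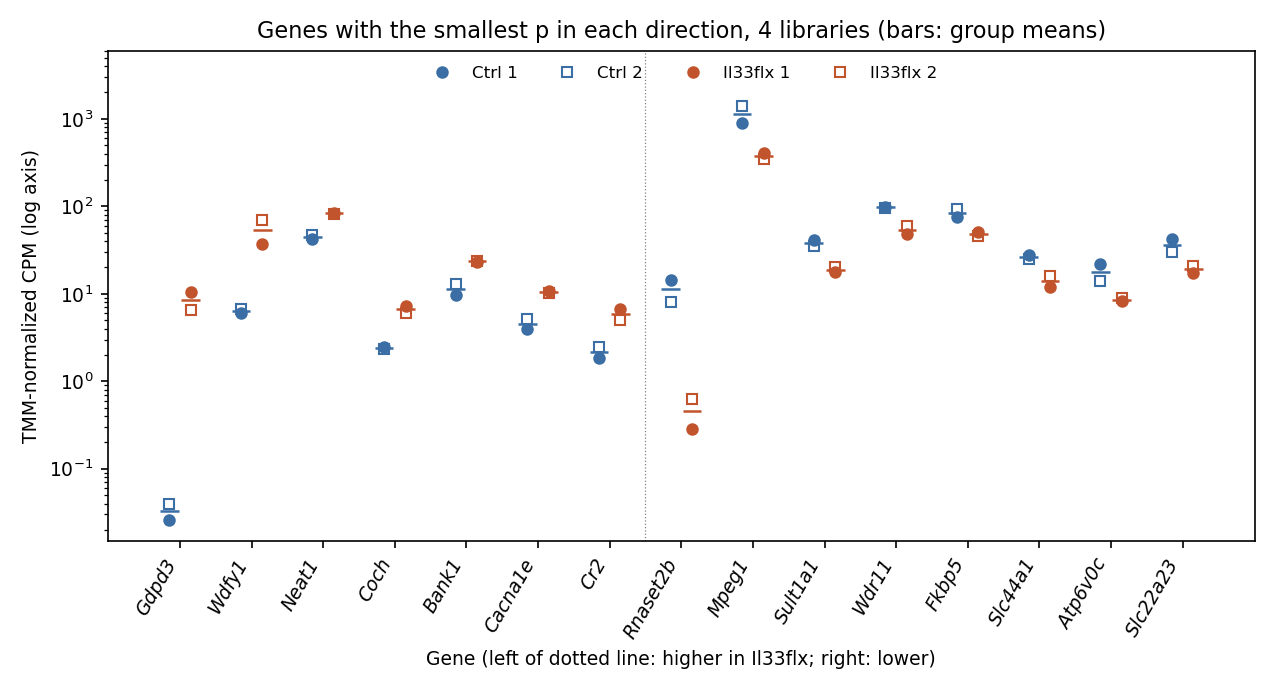
TMM-normalized CPM on a log axis of genes with the smallest p in each direction (7 higher and 8 lower in Il33flx), 1 point per library (blue, Ctrl; orange, Il33flx; filled circles, replicate 1; open squares, replicate 2), with a bar at each group mean. Gdpd3 lies at 8.40 CPM on average in Il33flx and 0.0330 CPM in Ctrl, and Mpeg1 at 375 and 1146 CPM.

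The authors' deposited table called 31 genes higher and 20 lower at an adjusted p below 0.05, and 19 of these 51 were immunoglobulin genes. All 51 were also tested here, and each had the same direction, an unadjusted p under 0.05 and groups that did not overlap in edgeR, while 1 was called. DESeq2 run on the deposited counts called 49 of the 51. In the authors' deposited table the log2 fold change was 7.97 for Gdpd3 (adjusted p = 2.75e-21), 3.06 for Wdfy1 (6.84e-14), -4.66 for Rnaset2b (1.41e-17) and -1.64 for Mpeg1 (5.99e-05).

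Erythroid and B cell marker genes had positive medians in Il33flx, with no single member past the threshold in edgeR with all libraries and no block. Among 18 erythroid and platelet genes, 17 had a positive log2 fold change, with a median of 1.17, and 11 were higher in both Il33flx libraries than in both Ctrl libraries, where chance gives 16.7%. Car1, a red cell carbonic anhydrase, had 0.278 ± 0.172 CPM in Ctrl and 3.51 ± 0.228 CPM in Il33flx, and the anion exchanger gene Slc4a1 had 0.0931 ± 0.132 and 4.62 ± 1.98 CPM. Over all genes tested 0 of the 18 passed, and adjusted over the list alone 6 passed, all higher. Only 2 of the 18 had at least 5 CPM in Ctrl. Car1 was called with DESeq2 (adjusted p = 4.31e-08), and Car1 and Slc4a1 were called by edgeR with the block, without Ctrl 1 and without Il33flx 1 (adjusted p = 0.00275 to 0.0179), but not without Ctrl 2 (0.119 for each) or Il33flx 2 (0.845 and 0.852). Among 20 B cell genes the median was 0.77, 14 were higher without overlap and 1, Igkc, was lower. Adjusted over the list alone 5 of them passed, all higher, with log2 fold changes of 2.91 ± 0.54 SE for Pax5, the B lineage transcription factor, and 1.15 ± 0.30 SE for the antigen receptor subunit gene Cd79a, and 0 passed over all genes tested. Pax5 was called with DESeq2 (adjusted p = 0.00795) and not with the block (0.145) or with a library left out (0.142 to 1). The abundant B cell transcript Ighm lay at 1073 ± 240 CPM in Ctrl and 974 ± 84.1 CPM in Il33flx. Camera with the preset correlation called the erythroid list (adjusted p = 2.8e-15) and the B cell list (adjusted p = 1.73e-09). Both calls were lost with an estimated correlation (adjusted p = 0.877 for each) and with fry (0.889 for each), and neither of these tests called any of the 34 lists. The estimated correlation also missed a list raised 2-fold in simulation (adjusted p = 0.22, camera), and fry was not simulated. Neither loss decides whether the lists changed. The B cell call was lost without Ctrl 2 (adjusted p = 0.0955, median 0.64), and the erythroid median fell to 0.38 without Il33flx 1.

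Medians above 0 were also found for neutrophil, basophil and proliferation genes, with no single member past the threshold in edgeR with all libraries and no block. Elane, the neutrophil elastase gene, had 7.87 ± 5.34 CPM in Ctrl and 24.9 ± 4.82 CPM in Il33flx, and Mpo, the myeloperoxidase gene, 72.1 ± 48.3 and 167 ± 33.7 CPM. The median over 19 neutrophil genes was 0.38 and 7 were higher without overlap, while 0 passed over all genes tested or adjusted over the list alone. Without Ctrl 1, where the neutrophil median was 0.17, Elane, Mpo and the granule protease genes Prtn3 and Ctsg were called higher (adjusted p = 0.00121 to 0.0181, edgeR), and with the block Elane was called (0.0286). None of these 4 was called with DESeq2 (adjusted p = 0.0697 to 0.618) or with another library left out (0.135 to 1). Among 14 basophil, mast cell and eosinophil genes the median was 0.53 and 5 were higher without overlap, and 0 passed by either adjustment. The median was 0.203 and the call was lost (adjusted p = 0.219) with the filter of 1 CPM in 2 libraries, and the median was 1.07 with no filter (0.00775). Without Ctrl 1 the median of this list was 0.88. Examples from this list lay at low counts, with Mcpt8, a basophil protease gene, at 0.730 ± 0.0361 and 2.17 ± 1.71 CPM. Among 40 proliferation genes 33 had a positive log2 fold change, with a median of 0.18, but only 2 were higher without overlap and 2 were lower, under the share of chance, and 0 passed by either adjustment. Birc5, the gene of the mitotic protein survivin, had 74.9 ± 19.7 and 108 ± 28.1 CPM. Camera called the neutrophil list (adjusted p = 3.37e-06), the basophil list (0.00567) and the proliferation list (0.00472) with the preset correlation, and none with an estimated one (adjusted p = 0.877 to 0.896). Without Il33flx 1 the neutrophil median was 0.04 (adjusted p = 0.0629) and the basophil list had an adjusted p of 0.459, which was 0.447 without Ctrl 2. The proliferation list had an adjusted p of 0.167 without Ctrl 1 and 0.921 without Il33flx 2.

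Genes of T cells and of mature DCs had negative medians in Il33flx, with higher values in Ctrl 1 than in Ctrl 2 for the examples given. Among 25 T cell and EL4 genes 21 had a negative log2 fold change, with a median of -0.32, and 9 were lower without overlap. The T cell receptor subunit gene Cd3e had 12.4 ± 2.30 CPM in Ctrl and 7.90 ± 1.71 CPM in Il33flx. Among 30 genes of mature and migratory DCs 24 were below 0, with a median of -0.28, but only 2 were lower without overlap and 1 was higher, under the share of chance. Ccr7, the receptor that guides DCs to lymph nodes, read 999 CPM in Ctrl 1, 489 in Ctrl 2, 475 in Il33flx 1 and 415 in Il33flx 2, and the actin-bundling gene Fscn1 read 227, 86.2, 96.7 and 78.1 CPM. In both lists 0 members passed over all genes tested or adjusted over the list alone. Camera called both with the preset correlation (adjusted p = 0.000543 and 0.00472), and neither with an estimated one (adjusted p = 0.877 and 0.881). Without Ctrl 1 the median was -0.04 for the T cell list (adjusted p = 0.167) and 0.11 for the mature DC list (0.213), and without Il33flx 2 the adjusted p was 0.0997 and 0.0706.

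Genes of lipid synthesis had a negative median in Il33flx, with no single member past the threshold in edgeR. Of 28 genes of cholesterol and fatty acid synthesis 21 had a negative log2 fold change, with a median of -0.22, and 15 were lower without overlap and 2 higher. Lss, the lanosterol synthase gene, had 48.8 ± 9.59 and 31.9 ± 5.54 CPM, and the fatty acid synthase gene Fasn 408 ± 51.8 and 294 ± 23.3 CPM. Scd1, a fatty acid desaturase gene, went the other way at 4.99 ± 0.294 and 8.05 ± 1.56 CPM. Small negative medians were also found for MHC class I and cross-presentation (-0.14, 26 genes, 21 negative), conventional DC identity (-0.13, 17 genes, 11 negative) and glycolysis and hypoxia (-0.14, 26 genes, 19 negative). Without overlap 2, 6 and 5 of their genes were lower and 0, 1 and 3 were higher. The peptide transporter gene Tap1 had 1600 ± 414 CPM in Ctrl and 1322 ± 75.3 CPM in Il33flx. In these 4 lists 0 members passed over all genes tested or adjusted over the list alone. Camera called them with the preset correlation (adjusted p = 0.00329 for lipid synthesis and 0.043 to 0.0471 for the others), and none with an estimated correlation (adjusted p = 0.877 to 0.895). The lipid list had an adjusted p of 0.0784 without Ctrl 2 and 0.244 without Il33flx 1. The other 3 lists lost their call without Ctrl 1 (adjusted p = 0.393 to 0.89), without Il33flx 1 (0.115 to 0.215), without Il33flx 2 (0.102 to 0.197), with the filter of 1 CPM in 2 libraries (0.0522 to 0.0537) and with library size alone (0.099 to 0.113), where their medians were -0.06 to -0.0476. The MHC class I and glycolysis lists also lost it with the block (0.0559 for each). Without Ctrl 1 the MHC class I median was 0.03, that of conventional DC identity -0.06 and that of glycolysis and hypoxia -0.03.

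**Figure D3:**
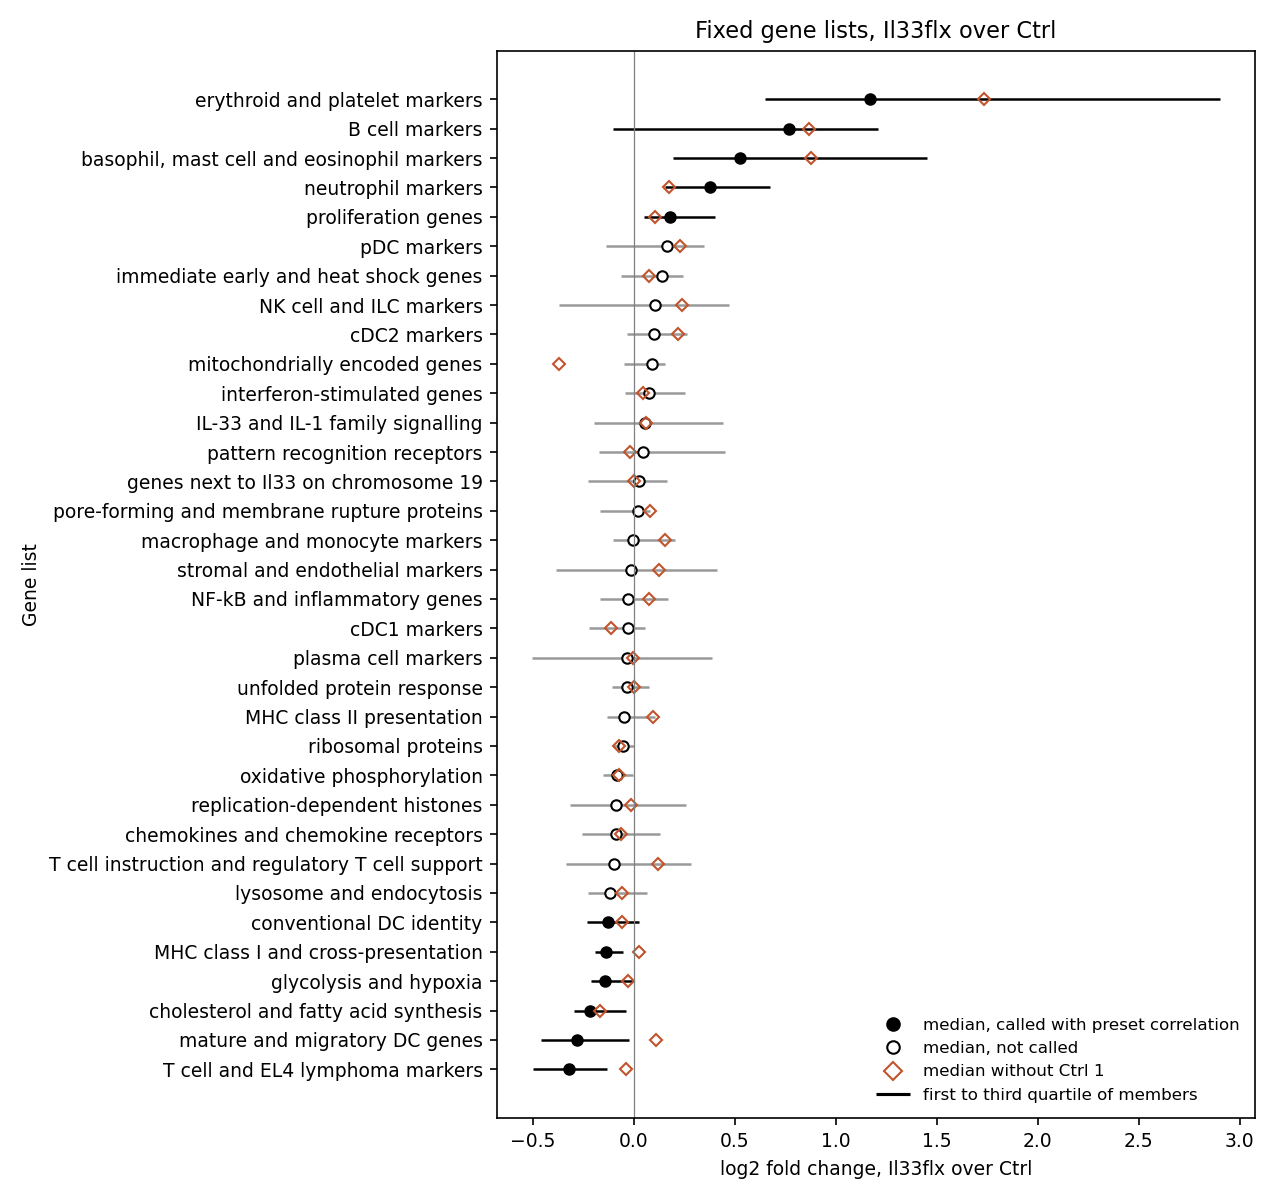
Median log2 fold change of Il33flx over Ctrl for the 34 tested gene lists (filled circles, called by camera with the preset correlation; open circles, not called), with lines from the first to the third quartile of members and diamonds at the median without Ctrl 1. The erythroid and platelet list has the highest median, 1.17, and the T cell and EL4 list the lowest, -0.32.

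The remaining 23 tested lists were not called (adjusted p = 0.0982 to 0.846, medians -0.12 to 0.16). They covered the type 1 and type 2 DC and plasmacytoid DC markers, MHC class II, IL-33 and IL-1 family signalling, interferon-stimulated and NF-kB genes, and macrophage, NK cell, plasma cell and stromal markers. Ribosomal, mitochondrial, oxidative phosphorylation, histone, stress and lysosomal genes, receptors of innate sensing, chemokines, factors of T cell instruction and the neighbours of Il33 made up the rest, with pore-forming proteins. In 7 of these lists the median, mean and test differed in sign. One member passed when adjusted over its list alone besides Mpeg1, the IgA heavy chain gene Igha, at 484 ± 185 CPM in Ctrl and 117 ± 23.7 CPM in Il33flx (adjusted p = 0.0057, edgeR). Over all genes Igha was called with DESeq2 (adjusted p = 7.77e-07) and by edgeR with the block (0.00307) and without Ctrl 1 (0.00189), but not with another library left out (0.111 to 0.875) or with all libraries and no block (0.551). The IL-33 and IL-1 family list had a median of 0.06 over 19 genes (adjusted p = 0.757), with Il1b at 385 ± 80.6 and 568 ± 114 CPM and the adaptor gene Myd88 at 237 ± 28.5 and 178 ± 15.5 CPM. The 11 tested neighbours of Il33 on chromosome 19 had a median of 0.03 (adjusted p = 0.757), and Cd274, which encodes PD-L1, had 56.9 ± 17.3 and 44.5 ± 10.9 CPM. Without Ctrl 1 camera with the preset correlation called the type 1 DC, ribosomal and mitochondrial lists lower (medians -0.11, -0.08 and -0.37). It called the type 2 DC and macrophage lists higher (0.22 and 0.15). An estimated correlation was not tried in that fit, which leaves 1 Ctrl library.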

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

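The values of single lists under each alternative were computed after the data had been seen, and the other alternatives were chosen beforehand. The counts of called genes, 1 higher and 0 lower in edgeR, stayed at these values with robust moderation, RLE factors, the filter of 1 CPM in 2 libraries, a threshold of 0.1 and without Il33flx 2. DESeq2 called 31 higher and 22 lower. limma-voom, library size alone and no filter called 0 higher. In these fits the adjusted p of Gdpd3 was 0.459, 0.124 and 0.175 with log2 fold changes of 7.72, 8.003 and 7.91. Leaving out 1 library gave 0 to 19 genes higher and 0 to 19 lower, and the cause was not tested. Il33 kept a negative log2 fold change in each fit, from -5.59 to -0.45 when 1 library was left out, the former with the remaining Il33flx library at 0 counts. It passed no threshold, and at 12 counts in Ctrl and 4 in Il33flx the depth limits what can be said of it.

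The number of lists called was 11 with camera, 0 with an estimated correlation and 0 with fry (smallest adjusted p = 0.877 and 0.485). Even at an unadjusted p under 0.05, the estimated correlation held 0 lists and fry 1. In simulation, with genes drawn independently, the estimated correlation also missed a list raised 2-fold, and fry was not simulated. That simulation cannot tell whether the preset correlation holds in these libraries. The other alternatives called 8 to 14 lists, and leaving out 1 library 7 to 10. The erythroid and platelet list was called in every one of the latter fits. With a library left out the median of the mature DC list ran from -0.58 to 0.11, that of MHC class I from -0.29 to 0.026 and that of proliferation genes from -0.00036 to 0.34. The shared replicate numbers are not stated to pair the libraries, and the differences between replicates 1 and 2 did not correlate between the groups across genes (r = -0.0323, rho = -0.0883). With the replicate number as a block, 19 genes were called higher and 14 lower, and 15 of these 33 were immunoglobulin genes.

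The filter of 1 CPM in 2 libraries removed Il33 and left 56 of the 60 named genes checked, so the others have no value there. Of the 60 genes, 13 passed the threshold with DESeq2 that did not in edgeR, and 0 changed direction with RLE factors or library size alone. Il1rl1, at most 1.03 CPM in a library, turned to -0.23 with limma-voom and -0.17 with the block, and ran from -1.56 to 1.07 with a library left out. Log2 fold changes also crossed 0 on leaving out a library for Cd274 (-0.64 to 0.0026), Xcr1 (-0.066 to 0.65), Ptprc (-0.10 to 0.73), H2-Ab1 (-0.25 to 0.066), Flt3 (-0.27 to 0.030), Sirpa (-0.0074 to 0.23), Fscn1 (-1.39 to 0.030) and Tap1 (-0.52 to 0.024). None of these was called in any fit named here. The causes were not tested.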

Other observations

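The tests on carried-over cells and on near-identical copies were set before their own results were known, and the other tests below were chosen only after the result was seen. Zfpm2, a GATA cofactor gene singled out after its values were seen, had 0 counts in both Ctrl libraries and 207 and 171 in the Il33flx libraries. Against a floor of 3 counts per Ctrl library it was at least 67.0-fold higher (adjusted p = 0.258, edgeR). The inducible heat shock genes Hspa1a and Hspa1b, a near-identical pair, had 31.6 ± 11.95 and 45.3 ± 21.9 CPM in Ctrl and 115 ± 77.0 and 184 ± 118 CPM in Il33flx (SD, n = 2, adjusted p = 0.995 for each, edgeR). Both were called with DESeq2 (adjusted p = 0.0252 and 0.00886), in the authors' deposited table (0.0418 and 0.0164), and by edgeR with the replicate number as a block (0.00899 and 0.00162) and without Il33flx 1 (0.00215 and 0.00137), but not with another library left out (0.171 to 1). Zfpm2 was called with DESeq2 and by edgeR with the block, without Ctrl 1 and without Il33flx 1. Xist, the X-inactivation RNA, read 18.8 CPM in Ctrl 1, 63.6 in Ctrl 2, 70.6 in Il33flx 1 and 80.2 in Il33flx 2. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in each library.

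Immunoglobulin segments varied widely between libraries of the same group. Of 140 tested variable segments, 53.6% differed between the groups by over 2-fold, with 25 higher and 39 lower without overlap. That is 45.7%, where chance gives 33.3% and the other genes gave 30.1%. Between the Ctrl libraries 62.1% of the segments differed by over 2-fold, and between the Il33flx libraries 52.1%. For the other genes the shares were 6.15% between groups, 14.1% between the Ctrl libraries and 5.34% between the Il33flx libraries. Shares within a group come from ratios of single libraries with 0.1 CPM added. Those between groups come from fitted changes over 2 libraries each, so the 2 kinds of share are not directly comparable.

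Mpeg1 was lower in Il33flx, and a lower share of macrophages and monocytes, which also express it, is argued against by their list, whose median log2 fold change was -0.00482 with a lower quartile of -0.10, far above -1.61. The difference did not rest on Ctrl 2 alone, since the log2 fold change of Mpeg1 was -1.246 without that library. Mpeg1 read 885 CPM in Ctrl 1 and 404 and 345 CPM in the Il33flx libraries. However, that fit rests on Ctrl 1, the library set apart on the first principal component. It has no measure of the spread between Ctrl libraries. A chromosome segment inherited with the floxed allele may still be the cause, because Mpeg1 lies 17.5 Mb from Il33 on the same chromosome. Of 68 tested genes between them 2.94% had an unadjusted p under 0.05, against 3.25% of other genes (one-sided Fisher's exact p = 0.653), which leaves a segment with a single changed gene possible. Loss of Il33 in DCs, the difference the design names, also stays open and was not tested apart from such a segment.

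The B cell and erythroid lists had positive medians in Il33flx (0.77 and 1.17), but only camera with the preset correlation called them (adjusted p = 0.877 with an estimated correlation and 0.889 with fry, for each), and 0 members passed over all genes in edgeR. A lower share of DCs would raise markers of all other cells alike, which as the whole cause is argued against by the T cell and EL4 median of -0.323. The upper quartile of that list, -0.133, lay below the lower quartile of the erythroid list, 0.648, and did so with each library left out. It lay below that of the B cell list, -0.103, by little, and not without Ctrl 2 (-0.218 against -0.247), and without Ctrl 1 the T cell median was -0.0383. The medians of neutrophil (0.38), basophil (0.53) and conventional DC identity genes (-0.13) go with a lower share of DCs. The medians of type 1 DC (-0.03), type 2 DC (0.10) and MHC class II genes (-0.05) showed no such fall. Those of macrophage and monocyte (-0.005), stromal (-0.01), plasma cell (-0.03) and NK cell genes (0.10) lay nearer 0. The DC identity median was -0.06 without Ctrl 1, and none of these lists was called with an estimated correlation. A lower share of DCs stays open as a part of the cause. Ctrl 1 alone does not account for the positive medians, since the median over both lists was 1.24 without it. More B cells and erythroid cells carried through the sort cannot be told apart from an effect of genotype by the share of markers higher in both Il33flx libraries than in both Ctrl libraries, 65.8% of the 38 members, which restates the pattern, as either would raise it. It lay above the 16.7% of chance and below the 75% set beforehand. The B cell list did not move as a whole, since the abundant Igkc was lower (449 ± 104 CPM in Ctrl and 305 ± 16.7 CPM in Il33flx). Igha, of the plasma cell list, was lower too (484 ± 185 and 117 ± 23.7 CPM), so Igkc does not decide on more B cells. The globin gene Hba-a1 was higher, with 0.920 ± 0.192 CPM in Ctrl and 3.63 ± 2.36 CPM in Il33flx. Of the 20 B cell members 11 had at least 5 CPM in Ctrl, and 2 of the 20 belong to another list. Of the 18 erythroid and platelet members only 2 had at least 5 CPM in Ctrl, so the median of that list rests mostly on genes at low counts. The gate on CD45 would remove mature red cells and that on CD11b and CD103 most B cells. The B cell list genes Igkc and Ighm were still read in both groups, so the gate does not exclude RNA of such cells. Both explanations stay open, and an effect of genotype was not tested.

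Genes with an unadjusted p under 0.01 clustered on chromosome 17, where 7 of them, none past the adjusted threshold in edgeR, lay between 5410870 and 7979824 (Tmem242, Dynlt1b, Tmem181b-ps, Tagap1, Rnaset2b, Fndc1 and Rsph3a), out of 32 tested in that 5 Mb window. Random placement of the 87 such genes reached 7 in any window in 8 of 10000 draws (one-sided permutation p = 9e-04). This argues against chance position if genes vary independently, as the draws assume. Neighbours whose counts vary together would make this p too small. Whether reads moved between near-identical copies stays open. The summed count with the same-family partner changed by less than 50% of the gene's own log2 change in 3 of 4 pairs (Rnaset2b, Tagap1 and Tmem181b-ps, not Rsph3a), but this gives no support, since it would do so in 4 of 4 pairs if the partner, the more abundant copy in Ctrl, had not changed. No partner was tested for Tmem242, Dynlt1b and Fndc1, and a strain difference in this segment stays open, since no strain is given in the sources used here.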
